A study of Homo sapiens
Mus musculus with 6 samples.

How the data were processed

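The 6 libraries hold RNA of co-cultures of human MCF-7 cells and mouse MSCs, 3 libraries from treatment with ATO at 5 µM and 3 from vehicle. Total RNA was extracted with a column kit, copied into double-stranded cDNA and made into libraries with a Nextera XT kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, STAR, RSEM 1.2.28 and DESeq2 and the builds GRCh38 and GRCm38. How human and mouse reads were told apart, which step used which build and whether counting used strand are not given in the sources used here, so genes that overlap others, or have antisense partners or close paralogs, are uncertain. Reads of mouse cells counted to human genes could not be excluded from these values.

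The deposited values are log2 expression per gene symbol. That the scale is log2 was read from the values, which are fractional and negative at the low end: 3879 of 37039 rows are exactly 0 in every library, and genes with few reads lie at floors that differ slightly between genes and libraries. This is the form of a regularized-log transformation, which pulls low values to the gene mean. The transformation is not given in the sources used here. If it is such a one, fold changes of weakly expressed genes are understated. Counts could not be had from these values, so read depth is unknown, no count model was fitted and no counting interval is given. Symbols of 27 rows have the form of dates, as a spreadsheet makes of gene names, and these rows were kept but not named. Of the rows, 99.0% matched a symbol or synonym in a RefSeq gene table of GRCh38, from which the chromosome, start and end are given (counted from 1).

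The test fixed before the data were examined for normalized values was limma on log2(value + 1). As the values are already log2, limma was run on them directly, without a pseudocount. A gene was tested if it was not 0 throughout and the mean of its values, taken back from the log2 scale (its normalized mean), was at least 1. limma 3.58.1 in R 4.3.3 compared ATO with vehicle with a mean-variance trend and no covariate. The Benjamini-Hochberg adjustment covered the 22905 genes tested, with a threshold of 0.05. Errors are SD over the 3 libraries of a group or the SE of limma's log2 fold change, which is ATO minus vehicle. An exact permutation test of 3 against 3 cannot give a p under 0.1, so limma's moderated test, which pools the spread over genes, was used. Gene lists were tested with camera (preset correlation 0.01, then an estimated one) and fry, adjusted over the 24 lists, and counts adjusted over the list alone are given beside those over all genes.

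Genes were named by a rule fixed before the data were examined. It took the 6 that rose and the 6 that fell most among genes past the threshold with a normalized mean of at least 10 and no overlap between groups. It also took up to 4 members of each list with the smallest p, and HMOX1, MT2A, MT1X, ESR1, TFF1, GLI1, CCL2, IL6 and MKI67. The text gives 1 to 4 of the members so taken for each list other than the ribosomal and mitochondrial ones, for which it gives none; HSPB1, STC2 and the members of the stromal, leukocyte and gene family sets were chosen after their values were seen. The procedure was tested on simulated values for the 22905 genes with 200 changed. Simulated errors were normal, independent between genes and of the spread that limma fitted. The procedure recovered 14% of changes of 0.5 on the log2 scale, 66% of changes of 1, 96% of 2 and 100% of 4, and 7 of 145 calls (4.83%) were false. The real data gave more calls and hold shifts shared between genes, so these shares need not hold for them.

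The planned comparison of mouse genes, the mouse gene lists, the share of human counts and the difference between species need mouse values and were not run. Alternatives tried were other filters on low values, leaving out mitochondrial genes, a replicate block, leaving out each library in turn, other scalings, limma without the trend, leaving out vehicle 1 and ATO 3, and a covariate. The covariate was the median deviation, per library, of 373 olfactory receptor genes.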

Results

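RNA was sequenced from 3D co-cultures of MCF-7 cells, an oestrogen receptor-positive human breast cancer line that carried a luciferase reporter here, with mouse mesenchymal stromal cells (MSCs). Each well received 200000 cells of each kind in serum-free medium on low-attachment plates. The cultures were exposed to 5 µM arsenic trioxide (ATO), an arsenical used against acute promyelocytic leukaemia, or to PBS as the vehicle, for under 48 h. There were 3 libraries per group. The table analysed holds log2 expression of 37039 human symbols, and mouse genes were not analysed here. The values are read as human transcripts, though reads of mouse cells counted to human genes could not be excluded. Read depth is unknown, since the values are not counts. Over genes with a normalized mean of at least 10, Pearson correlations across genes were 0.973 to 0.993 within the groups and 0.945 to 0.966 between them; genes are not independent replicates. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

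The comparison of ATO with vehicle asked which human genes of the co-culture differ in expression under the drug. Of the genes past the threshold with a normalized mean of at least 10 and no overlap between groups, MT2A, a metallothionein gene (GRCh38 chromosome 16, 56608584 to 56609497), rose most. It went from a log2 expression of 5.83 ± 0.19 to 10.60 ± 0.11 (SD, n = 3), which is 27.2-fold. HMOX1, the inducible haem oxygenase (chromosome 22, 35381096 to 35394207), went from 8.12 ± 0.12 to 12.31 ± 0.21, or 18.2-fold. MT1X rose 18.3-fold, the collagenase gene MMP1 22.5-fold, FAM129A 16.5-fold and SLC7A11, which encodes the cystine transporter subunit, 15.9-fold. The genes that fell most did so by less. RAMP3, which encodes a receptor activity-modifying protein, fell from 8.32 ± 0.23 to 5.79 ± 0.21, so that vehicle was 5.77-fold higher. It was followed by GJA1 (the gap junction protein connexin 43), SULF1 (an extracellular sulfatase), IGFBP5, GLRA3 and BMP5, which were between 3.92- and 4.88-fold higher in vehicle. The 12 genes named here had adjusted p-values between 8.8e-13 and 0.000525 in limma, and in each the 3 ATO libraries lay on one side of the 3 vehicle libraries.

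Of 22905 genes tested, 2487 (10.9%) passed an adjusted p of 0.05 in limma, 1408 of them higher and 1079 lower under ATO. Changes of at least 2-fold numbered 347 upward and 283 downward, and those of at least 4-fold 43 and 3. The groups did not overlap in 5719 of the genes tested (25%), where chance gives 10%. The total dropped to 1342 without ATO replicate 1, to 1542 without ATO replicate 2 and to 1655 without vehicle replicate 2, and the count of lower genes went to 1888 without vehicle replicate 1, when 46.4% of called genes were higher against 56.6% with all libraries. Vehicle 1 and ATO 3 held higher values of weakly expressed genes than the other libraries of their groups (median deviation of genes at a mean log2 of 0 to 4, 0.51 and 0.22), and 4439 genes passed without these 2 libraries.

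**Figure D1:**
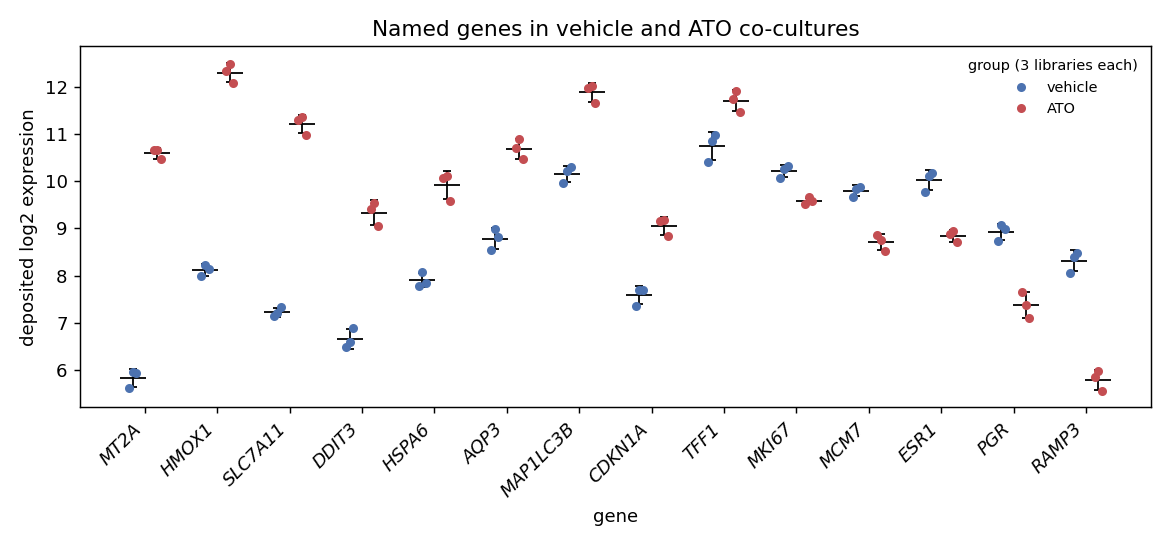
Deposited log2 expression (y axis) of 14 named genes (x axis) in the 3 vehicle (blue) and 3 ATO (red) libraries; horizontal bars are means and error bars SD. For each gene the libraries of the groups do not overlap, from MT2A (5.83 to 10.60) to RAMP3 (8.32 to 5.79).

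Gene lists fixed before the data were examined were tested with camera, with a preset correlation between genes of 0.01. Camera compares a list with the other tested genes, so its direction is relative to them. By this test 16 of 24 lists passed an adjusted p of 0.05, 11 upward and 5 downward. With an estimated correlation none did, while 5 had an unadjusted p under 0.05 in camera. With fry, which asks whether the members of a list move one way on balance, 10 passed. The lists that passed camera but not fry were hypoxia and glycolysis (fry adjusted p = 0.417), chaperones of the endoplasmic reticulum (0.253), luminal identity (0.232), mitosis (0.129), p53 targets (0.111) and cholesterol synthesis (0.0854). With an estimate, camera also tests on the few residual degrees of freedom of so few libraries. The loss of calls therefore does not by itself show that list members vary together. As no call of camera held with an estimated correlation, the account of each list starts from the counts of its members that passed limma. Other filters and scalings, a fit without vehicle 1 and ATO 3, and one with the median deviation of olfactory receptor genes as a covariate were also run; the filter at 30, the scalings and both fits were chosen after the data were seen.

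Genes of the metal response rose. Of 5 members tested, 4 rose and none fell (5 rose when adjusted over the list alone), with a median log2 fold change of 2.59. Besides MT2A and MT1X these were MT1F, 6.01-fold higher, and SLC30A1, which exports zinc, 3.63-fold higher. The other listed metallothioneins (MT1A, MT1B, MT1E, MT1G, MT1H and MT1M) lay below the filter on low values. Metallothionein genes are near-identical copies, so the division of reads among them is uncertain. The list passed camera (adjusted p = 3.9e-15; adjusted p = 0.117 with an estimated correlation) and fry (adjusted p = 0.000411).

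Targets of NRF2, the transcription factor of the antioxidant response, rose nearly throughout. Of 28 tested, 27 rose and none fell (28 rose when adjusted over the list alone), with a median log2 fold change of 1.36. Besides HMOX1 and SLC7A11, the 2 members with the smallest p-values were AKR1C1, an aldo-keto reductase with close paralogs, at 11.4-fold, and SRXN1 (sulfiredoxin) at 5.19-fold. Camera gave an adjusted p of 2.7e-47 (adjusted p = 0.150 with an estimated correlation) and fry 0.00178. Genes of arsenic transport and metabolism were mixed. Of 13 tested, 4 rose and 1 fell, and the same counts held when adjusted over the list alone. AQP3, an aquaglyceroporin, rose 3.75-fold and ABCC1, an efflux pump, 1.57-fold, while SLC39A8, a metal importer, was 1.57-fold higher in vehicle and lost its call without vehicle replicate 2 (limma adjusted p = 0.0575). The median log2 fold change of this list was 0.11 (camera adjusted p = 0.0430; adjusted p = 0.302 with an estimated correlation). Its camera call ended without vehicle replicate 1 (median 0.25, adjusted p = 0.0860) and without ATO replicate 2 (adjusted p = 0.0611), and its median was 0.18 without ATO replicate 1 and 0.0161 without ATO replicate 3. The call also ended with a filter at a normalized mean of 30 (median 0.36, adjusted p = 0.186), without vehicle 1 and ATO 3 (0.19, adjusted p = 0.102) and with the covariate (0.12, adjusted p = 0.0635).

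The integrated stress response governed by ATF4 was also higher. Of 27 members tested, 22 rose and none fell (25 rose when adjusted over the list alone), with a median log2 fold change of 1.26. DDIT3, which encodes the stress factor CHOP, rose 6.41-fold, SESN2 4.72-fold, ASNS (asparagine synthetase) 4.69-fold and SLC7A5, an amino acid transporter, 3.94-fold. Camera gave an adjusted p of 2.4e-39 (adjusted p = 0.150 with an estimated correlation). Of 24 heat shock genes, 9 rose and 1 fell (13 and 1 when adjusted over the list alone). These counts were 18 and 1 both with the covariate and without vehicle 1 and ATO 3. HSPA6 rose 4.06-fold and SERPINH1, a collagen chaperone, 1.67-fold. The member that fell was the small heat shock gene HSPB1, with a log2 fold change of -0.60. The list's median was 0.56 (camera adjusted p = 3.2e-09; adjusted p = 0.374 with an estimated correlation). HSPA genes share sequence, so single members are uncertain. Of 21 chaperones of the endoplasmic reticulum, 6 rose and 1 fell (7 and 2 when adjusted over the list alone), HERPUD1 by 2.14-fold and HYOU1 by 1.68-fold upward. Their median log2 fold change was 0.23 (camera adjusted p = 0.0103; adjusted p = 0.682 with an estimated correlation), and camera's call ended without vehicle replicate 1 (median 0.0785, adjusted p = 0.270) and without ATO replicate 2 (adjusted p = 0.0605). It also ended with a filter at 5 (adjusted p = 0.0751) or 30 (adjusted p = 0.238), under quantile normalization (median 0.0979, adjusted p = 0.219) and with the covariate (0.13, adjusted p = 0.0675). Of the same 21, 9 rose and 7 fell with the covariate, and 9 and 5 without vehicle 1 and ATO 3.

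Genes of protein breakdown were higher under ATO. Of 28 proteasome genes, 26 rose and none fell, also when adjusted over the list alone. Their median log2 fold change was 0.73, with PSMD1 at 2.01-fold and PSMC4 at 1.95-fold. Camera gave an adjusted p of 2.7e-23 (adjusted p = 0.302 with an estimated correlation). Of 20 autophagy and lysosome genes, 15 rose and none fell (17 rose when adjusted over the list alone), with a median of 0.65. Examples were CTSL, a lysosomal protease, at 3.65-fold, MAP1LC3B, which encodes an autophagosome membrane protein, at 3.32-fold, and its relative GABARAPL1 at 3.21-fold. The camera adjusted p was 2.6e-18 (adjusted p = 0.169 with an estimated correlation).

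**Figure D2:**
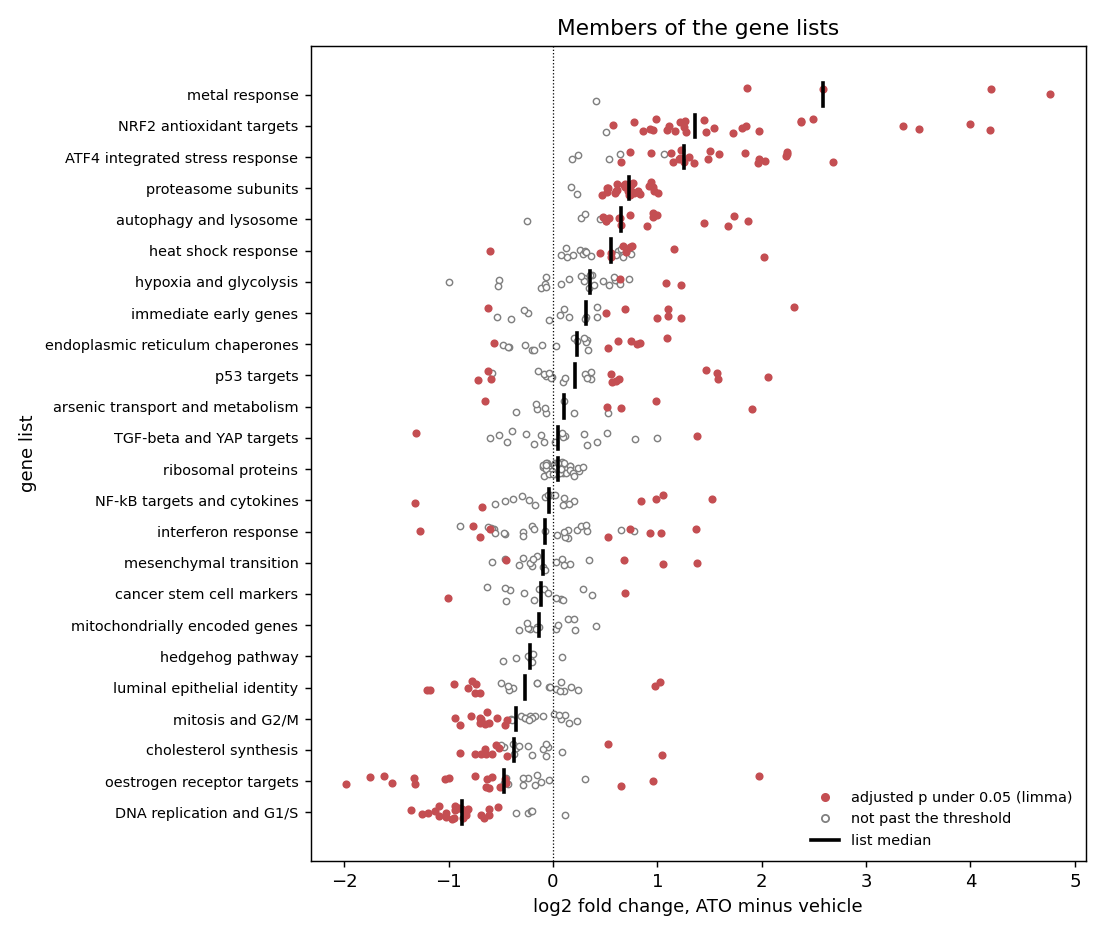
Log2 fold change, ATO minus vehicle (x axis), of each tested member of the 24 gene lists (y axis), 3 libraries per group; filled red points passed limma's adjusted p of 0.05, open points did not, and black bars are list medians. Medians run from 2.59 for the metal response to -0.87 for DNA replication.

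Replication genes were lower. Of 28 genes of DNA replication and the G1/S transition, 23 fell and none rose (24 fell when adjusted over the list alone), with a median log2 fold change of -0.87. UHRF1, which maintains DNA methylation, was 2.56-fold higher in vehicle, the transcription factor gene E2F1 2.39-fold, MCM7 of the replicative helicase 2.12-fold and PCNA 2.04-fold. The camera adjusted p was 2.7e-23 (adjusted p = 0.169 with an estimated correlation). Of 28 mitotic genes, 12 fell and none rose (13 fell when adjusted over the list alone), with a median of -0.35. The number that fell was 21 with the covariate and 18 without vehicle 1 and ATO 3. CDK1 was 1.91-fold and MKI67, the gene of the proliferation marker Ki-67, 1.55-fold higher in vehicle, and MKI67 lost its call without ATO replicate 1 (limma adjusted p = 0.0761). Camera gave the mitotic list an adjusted p of 8.5e-07 (adjusted p = 0.584 with an estimated correlation) and fry 0.129. Targets of p53, the damage-responsive tumour suppressor, included CDKN1A, which encodes the cell cycle inhibitor p21, up 2.77-fold, GADD45A, up 3.00-fold, and the death receptor gene TNFRSF10B, up 2.98-fold. Of 24 tested, 8 rose and 3 fell (9 and 4 when adjusted over the list alone). The median log2 fold change was 0.21 (camera adjusted p = 0.00121; adjusted p = 0.622 with an estimated correlation, and 0.0697 with a filter at 30).

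Genes of the oestrogen receptor programme were mostly lower. ESR1, the gene of the receptor itself (chromosome 6, 151656672 to 152129619), fell from 10.03 ± 0.21 to 8.85 ± 0.13, so that vehicle was 2.26-fold higher. Of 30 receptor targets, 16 fell and 3 rose (18 and 3 when adjusted over the list alone), with a median log2 fold change of -0.47. ELOVL2, a fatty acid elongase gene, was 3.37-fold and PGR, the progesterone receptor gene, 2.91-fold higher in vehicle. The 3 that rose were SLC7A5 and STC2, which also stand in the ATF4 list, and TFF1, a classical receptor target that was 1.94-fold higher under ATO (limma adjusted p = 0.00423, and 0.0555 without the mean-variance trend). The list's camera adjusted p was 4.8e-09 (adjusted p = 0.374 with an estimated correlation). Of 24 genes of luminal epithelial identity, ESR1 among them, 8 fell and 2 rose (10 and 2 when adjusted over the list alone), with a median of -0.27. In this list 16 fell and 3 rose with the covariate, and 12 fell and 3 rose without vehicle 1 and ATO 3. MUC1 was 2.31-fold higher in vehicle, while CLDN7, a tight junction gene, rose 2.04-fold. The list passed camera (adjusted p = 0.00709; adjusted p = 0.693 with an estimated correlation), but not without vehicle replicate 2 (0.0607), vehicle replicate 3 (0.105) or ATO replicate 3 (0.111). Of 24 cholesterol synthesis genes, 9 fell and 2 rose (12 and 2 when adjusted over the list alone), with a median of -0.38. Here 16 fell and 2 rose with the covariate, and 14 fell and 2 rose without vehicle 1 and ATO 3. LSS, which forms lanosterol, was 1.86-fold higher in vehicle, while SC5D, a late step, rose 2.06-fold. Camera gave an adjusted p of 5.4e-05 (adjusted p = 0.518 with an estimated correlation).

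Of 20 immediate early genes, 7 rose and 1 fell (9 and 2 when adjusted over the list alone), with a median log2 fold change of 0.31. FOSL1 rose 4.96-fold, ATF3, which also stands in the ATF4 list, 2.34-fold and EGR1 2.15-fold. The list's camera adjusted p was 6.3e-05 (adjusted p = 0.329 with an estimated correlation), and its median was 0.17 without vehicle replicate 1. With the covariate 11 of its members rose and 4 fell. Of 26 hypoxia and glycolysis genes, 3 rose and none fell (4 rose when adjusted over the list alone). VEGFA, an angiogenic factor gene, rose 2.11-fold. Their median was 0.35 (camera adjusted p = 0.00181; adjusted p = 0.682 with an estimated correlation), and without vehicle replicate 1 it was 0.05 and camera's direction turned (adjusted p = 0.849). The counts of this list depended on the fit: 8 rose and 5 fell without vehicle 1 and ATO 3 (median 0.10, adjusted p = 0.163), and 12 rose and 6 fell with the covariate. Camera's call also ended with a filter at 30 (adjusted p = 0.0625).

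The remaining lists did not pass camera. Of 20 NF-kB targets and cytokines, 4 rose and 2 fell (4 and 3 when adjusted over the list alone). ICAM1 rose 2.08-fold and LIF 2.87-fold. CXCL12, a chemokine gene that also stands in the list of oestrogen receptor targets, was 2.50-fold higher in vehicle. The list's median was -0.04, its mean 0.04 and camera's direction upward (adjusted p = 0.804). CCL2 had a log2 fold change of -0.17 ± 0.32 (SE, limma adjusted p = 0.869), and IL6 lay below the filter on low values. Of 33 interferon response genes, 5 rose and 4 fell (6 and 5 when adjusted over the list alone, and 7 and 8 with the covariate). HLA-A rose 2.58-fold and HLA-C 2.06-fold, though HLA genes share reads, and OAS3 was 1.70-fold higher in vehicle. The median was -0.07 and the mean -0.04, while camera's direction, relative to the other genes, was upward (adjusted p = 0.804). Of 19 genes of mesenchymal transition, 3 rose and 1 fell, also when adjusted over the list alone. TGFBI rose 2.60-fold and ITGB1 2.08-fold. The median was -0.10, against a mean of 0.04 and an upward direction in camera (adjusted p = 0.428). Of 16 cancer stem cell markers, HES1 rose 1.61-fold and SOX9 was 2.01-fold higher in vehicle, and 14 did not pass (the same when adjusted over the list alone; 2 rose and 4 fell with the covariate). This list had a median of -0.11 (camera adjusted p = 0.677). These medians moved when 1 library was left out, and so did the median over all tested genes. The latter was -0.07 with all libraries, 0.03 without vehicle replicate 1 and -0.12 without ATO replicate 3. The moves need therefore not be particular to these lists. Under the covariate fit the medians were 0.0075 (NF-kB), 0.0111 (interferon), 0.0154 (mesenchymal) and -0.0162 (stem cell). The NF-kB median turned positive without vehicle replicate 1 (0.0512) and ATO replicate 1 (0.0291), and lay between -0.19 and -0.0128 without any 1 of the other libraries. The interferon median turned positive without vehicle replicate 1 (0.0369), ATO replicate 1 (0.0223) and ATO replicate 2 (0.0724), and was -0.20 without vehicle replicate 3 and -0.21 without ATO replicate 3. The mesenchymal median was 0.12 without vehicle replicate 1, -0.20 without vehicle replicate 3, -0.0330 without ATO replicate 2 and -0.25 without ATO replicate 3. The stem cell median was -0.0655, -0.24 and -0.19 without vehicle replicates 1, 2 and 3, and -0.0617, -0.0181 and -0.29 without ATO replicates 1, 2 and 3.

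None of 8 hedgehog pathway genes passed limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. With the covariate 2 fell, and 1 fell without vehicle 1 and ATO 3. GLI1, the pathway's transcription factor and target gene, was weakly expressed, at 1.70 ± 0.18 in vehicle and 1.35 ± 0.55 under ATO, with a log2 fold change of -0.35 ± 0.37 (SE, limma adjusted p = 0.724). The list's median was -0.22 (camera adjusted p = 0.270), with -0.12 without vehicle replicate 1, -0.0758 without ATO replicate 2 and -0.36 without ATO replicate 3. Of 20 TGF-beta and YAP targets, TGFBI rose and SMAD6 was 2.48-fold higher in vehicle (2 rose and 3 fell when adjusted over the list alone, and 5 and 4 with the covariate). Their median was 0.05 (camera adjusted p = 0.544), with -0.0039 without vehicle replicate 1, -0.0239 without vehicle replicate 2, 5.3e-05 without ATO replicate 1 and 0.0045 without ATO replicate 2. None of 45 ribosomal protein genes passed limma, over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05, while 3 rose and 14 fell with the covariate. Their median of 0.05 (camera adjusted p = 0.335) became -0.11 under quantile normalization (adjusted p = 1.4e-08) and -0.07 with the covariate (adjusted p = 0.0236). With 1 library left out, the median ran from -0.12 without vehicle replicate 1 (adjusted p = 0.0860) to 0.16 without ATO replicate 3 (adjusted p = 0.00969), and the list also passed upward without vehicle replicate 3 (0.13, adjusted p = 0.0192). The median was 0.12 without vehicle replicate 2, 0.0178 without ATO replicate 1 and -0.0212 without ATO replicate 2. None of the 13 mitochondrially encoded genes, taken as a sign of RNA quality, passed limma, over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05. With the covariate 4 of them rose and 7 fell, and 1 rose and 2 fell without vehicle 1 and ATO 3. Their median was -0.13 (camera adjusted p = 0.804; -0.0576 without ATO replicate 3), and it was -0.34 under quantile normalization, where the list passed downward (adjusted p = 6.9e-09). Mitochondrial genes took 13.4% to 13.8% of the normalized sum in the vehicle libraries and 11.8%, 11.9% and 13.2% in the ATO libraries, so each ATO library lay lower. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give.

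**Figure D3:**
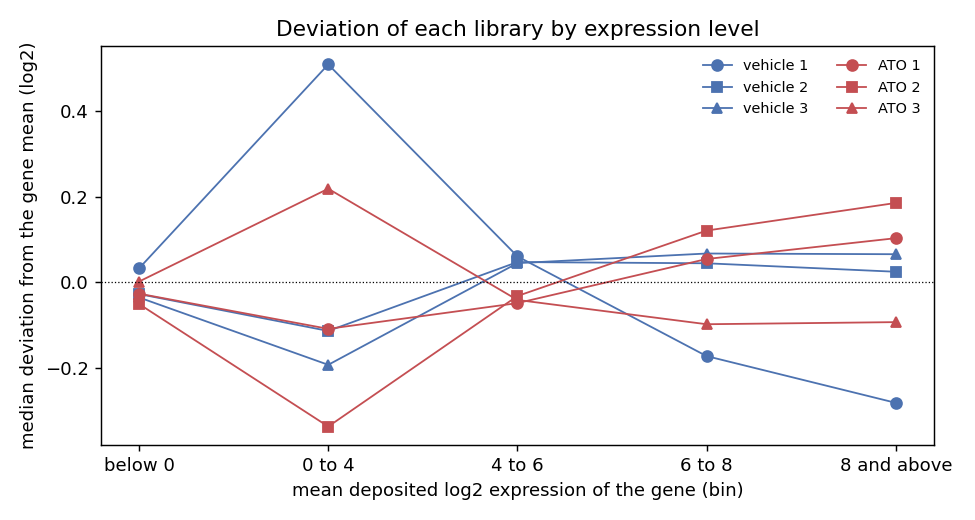
Median deviation of each library from the gene mean (y axis, log2) for genes binned by mean deposited log2 expression (x axis); blue lines are vehicle and red lines ATO libraries, replicates by marker. In the bin from 0 to 4, vehicle 1 (0.51) and ATO 3 (0.22) lie above the other 4 libraries, and in the bin of 8 and above they lie below them (-0.28 and -0.09).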

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

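The stricter filter at 30, the scalings, limma without the trend, the fits without vehicle 1 and ATO 3 and the covariate of olfactory receptor genes were chosen after seeing the data. Other normalizations of counts, count tests, count filters and pseudocounts, fixed before the data were examined, need counts or linear values and were not run. Of the 2487 genes called, 0 changed sign under any setting, though the number called moved. Under the other filters, the replicate block and limma without the trend, fold changes are the same by construction, so signs could not change. In the other settings a kept sign says little, as these genes were picked by their calls. Without a filter 1613 passed (876 higher, 737 lower), where more genes were tested; 2832 passed at a minimum of 5, 2972 at 30 and 2506 without mitochondrial genes. Leaving out 1 library gave 1342 to 3520 genes, 749 to 1632 higher and 593 to 1888 lower. Centring each library on the median of its genes with a normalized mean of at least 10 gave 4151 (2320 higher, 1831 lower), quantile normalization 4529 (2230, 2299), limma without the trend 1019 (538, 481), leaving out vehicle 1 and ATO 3 4439 (2472, 1967) and the covariate 6228 (3062, 3166); the cause was not tested. All 2487 were among the 6228 and 970 among the 1019. The replicate block gave 2281. Deviations of same-numbered libraries correlated at -0.16, 0.46 and -0.57, and of all libraries only vehicle 2 correlated best with its own number. Vehicle 1 and ATO 3, the libraries with high values of weakly expressed genes, correlated at 0.69. Such a shared shift can hide a pairing, so whether the replicate numbers pair the libraries stays open. Of 103 named genes 85 passed; 22 lost their call without the trend (TFF1, VEGFA, ABCC1, HES1, HLA-C and MKI67 among them), 6 without ATO replicate 1 and 5 without ATO replicate 2, 14 gained one with the covariate, and none reversed. Of 24 lists, 16 passed, 13 to 16 with 1 library left out, 12 to 17 under the other filters, scalings and fits, 0 with an estimated correlation and 10 with fry. Camera's direction for the hypoxia list turned without vehicle replicate 1, though its median stayed positive (0.0549). The highest median of this list with 1 library left out was 0.526. Ribosomal proteins turned under quantile normalization (-0.11) and with the covariate (-0.0679). Without vehicle 1 and ATO 3, 18 heat shock genes rose in place of 9 and 18 mitotic genes fell in place of 12; with the covariate 21 mitotic, 16 luminal and 16 cholesterol genes fell in place of 12, 8 and 9. Depth is unknown, so what it limits could not be measured. In the simulated data 14% of changes of 0.5 on the log2 scale were recovered.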

Other observations

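The tests of gene families, the reading of marker lists, the tests of explanations and the splits in this part were chosen after the results were seen. To look beyond the fixed lists, 148 families of protein-coding genes that share a symbol root were tested with camera, and 6 passed an adjusted p of 0.05 with the preset correlation. With an estimated correlation none passed (adjusted p = 0.997 for each of the 6), and 1 family had an unadjusted p under 0.05. Of 20 collagen genes (COL) tested, 5 fell and none rose in limma, and the count that fell was 5 with any 1 library left out and under the other scalings, 4 without the mean-variance trend, 4 of the 8 tested with a filter at 30, and 7 with the median deviation of olfactory receptor genes as a covariate. COL21A1 had a log2 fold change of -1.46 ± 0.25 (SE), COL3A1 of -1.22 ± 0.19, COL4A5 of -1.20 ± 0.22, COL5A2 of -1.19 ± 0.21 and COL18A1 of -0.61 ± 0.13. Of 15 semaphorin genes (SEMA), which encode guidance cues, 5 fell, 1 rose and 9 did not pass; 3 fell without the trend and 9 with the covariate. SEMA3E had a log2 fold change of -1.39 ± 0.15 and SEMA5A of -1.31 ± 0.16, while SEMA3B rose by 0.98 ± 0.13. Of 18 autophagy genes with the root ATG, 8 rose and none fell, 2 of them (ATG101 and ATG2A) already counted in the autophagy and lysosome list. ATG4A rose most, by 1.10 ± 0.17; 2 rose without the trend, 5 without ATO replicate 1, 5 without ATO replicate 2, 5 without a filter and 12 with the covariate. The other 3 families, MCM (7 of 10 fell), PSMD (10 of 14 rose) and HSPA (6 of 13 rose, 1 fell), each have 7 members in the fixed lists.

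Marker lists written for the mouse cells were read on the human symbols. Of 30 extracellular matrix genes, 2 rose (LOXL2 and SERPINH1) and 5 fell (COL3A1, COL5A2, LOXL1, FN1 and THBS1). FN1 lost its call when any 1 library other than vehicle 1 was left out, with limma adjusted p-values of 0.128 without vehicle replicate 2, 0.129 without vehicle replicate 3, 0.181 without ATO replicate 1, 0.0538 without ATO replicate 2 and 0.0751 without ATO replicate 3. FN1 also lost it under the replicate block (limma adjusted p = 0.0698), without a filter (0.0704) and without the mean-variance trend (0.188). Of 17 stromal markers, ITGB1 rose and CXCL12 fell, both of them already counted in the fixed lists. Of 17 markers of bone, cartilage and fat lineages, RUNX2 (-0.66 ± 0.13, SE) and SOX9 (-1.01 ± 0.17) fell. None of 12 endothelial markers passed limma, and 0 had an unadjusted p under 0.05. Of 12 macrophage and leukocyte markers 1 passed: CD68, which encodes a lysosomal glycoprotein, rose by 2.86 ± 0.26 (7.28-fold), while PTPRC, with a log2 fold change of 0.03 ± 0.45, and CD14, with one of -0.0048 ± 0.38, did not.

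The first pattern is technical in form. Genes with a mean log2 expression of 0 to 4 lay higher in vehicle 1 and in ATO 3 than in the other libraries of their groups. A background of reads unrelated to expression, such as genomic DNA, and a lower depth of these libraries both stay open. The shift of 373 olfactory receptor genes, which neither cell type is known to use, was 0.50 (95% bootstrap interval 0.43 to 0.54) in vehicle 1 and 0.26 (0.25 to 0.31) in ATO 3, but these genes are themselves weakly expressed, so it restates the pattern and supports neither. Mouse stromal transcripts counted to human genes cannot be told apart from them: the extracellular matrix list shifted less than the olfactory receptor genes in vehicle 1, by -0.27 (-0.58 to 0.22), and more in ATO 3, by 0.0647 (-0.29 to 0.18), and both intervals hold 0. The bootstraps resampled genes, which share the shift of a library, so their intervals hold no spread between libraries. The matrix list and the olfactory receptor genes also lay at unlike levels (median log2 expression 4.52 and 0.30 in vehicle 1), and the shift depends on level. All 30 genes of the matrix list passed the filter on low values, with COL1A1 at a mean log2 expression of 5.24 and SPARC at 1.24. Depth was not tested, as it is unknown. No biological explanation was tested, as the affected libraries belong to both groups.

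The second pattern is that every list call of camera was lost with an estimated correlation, although most members of several lists passed one by one. The component that olfactory receptor genes share with other weakly expressed genes is a candidate explanation, as it makes members of a list vary together. The median estimated correlation over the 24 lists was 0.46, and it was 0.0593 with the median deviation of olfactory receptor genes as a covariate, lower in 20 lists. Even then camera passed only 1 list, DNA replication and G1/S (adjusted p = 0.0303), and the next lowest adjusted p was 0.0643. The covariate was taken from the same 6 libraries, so the fall in correlation alone does not show that this component explains the loss. No other covariate was tried. With an estimate, camera also tests on the few residual degrees of freedom of so few libraries, which can end calls without correlation. The arsenic transport list had an estimated correlation of -0.0446, below the preset one. Its unadjusted camera p still rose from 0.0287 to 0.0815, so members varying together cannot account for the loss in that list. How the loss in the other lists divides between correlation and few degrees of freedom was not tested.

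The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave the most genes (1 of 10 splits reached 2487), and the highest other split gave 0 in limma, with up to 3206 at an unadjusted p under 0.05. For lists in camera with the preset correlation, the real split gave 16 (1 of 10 splits reached it) and the highest other 13. The other splits called 10 to 13 lists. Each of them puts both treatments in both groups, which leaves part of the treatment difference in the contrast and adds it to the spread, so neither the 0 genes nor the 10 to 13 lists show how often chance alone gives calls.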
